A study of Mus musculus with 18 samples.

How the data were processed

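RNA was measured by sequencing in 18 libraries of sorted mouse CD4 T cells from the small intestine. Donor T cells came from mice cloned from the nucleus of a peripherally induced regulatory T cell, on a RAG1-deficient background with a Foxp3-GFP reporter, so that the transferred cells shared 1 T-cell receptor. They were moved into hosts lacking T-cell receptor alpha and beta chains and recovered after 6 weeks. Per the labels, RNA was purified on beads from lysed cells and libraries were made with Nextera XT using 6 and 3 index adapters for the 2 index reads, all pooled. The submitters' processing notes name TopHat, HTSeq and the mm10 mouse build, which is GRCm38, without versions.

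The deposited table gives 1 normalised signal per gene and library for 38392 Ensembl gene identifiers, of which 36639 were found in GENCODE M21 and 1125 had no symbol. The signal deposited by the authors is a read count multiplied by 1 factor per library, rounded to 2 decimals, which was settled from the values themselves: 100% of the values above 0 in each library were whole multiples of 1 step, within a tolerance of 0.1 of a step. In IEL SP library 1 the step was 1.00139, too near to 1 for low values alone to show it. How the factors were computed is not stated. Dividing by the step recovered whole reads, from 5093955 to 8851347 per library with a median of 5903164.5, and the normalised totals ran from 5522793 to 7467918. A value is called a normalised count here. Reads amplified by PCR without molecular identifiers are not independent molecules, so floors based on read counts cover counting error only.

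Groups came from the labels, with 3 libraries in each of 6 groups: intraepithelial (IEL) or lamina propria (LP) cells that were CD4+CD8α+ (DP), CD4+Foxp3+ (TR) or negative for both CD8α and Foxp3 (SP). The labels call the libraries biological replicates but do not give the animals behind them, so p-values measure the spread between libraries and nothing beyond it. Libraries with the same replicate number were not paired: across the 45 pairs of groups and numbers, correlations of residuals ran from 0.00053 to 0.0887 with a median of 0.0385, and 0 exceeded 0.1. All were above 0, however, and all 18 libraries correlated most, on average over the other groups, with libraries of their own number. Something shared within a number is therefore likely, and p-values without the replicate block ignore it.

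The groups, comparisons, tests, fixed gene lists, rule for naming genes and planned settings were chosen before the data were examined. Normalised counts were taken to log2 after adding 1. The 15472 genes with at least 10 in at least 3 libraries were fitted in 1 limma model over all 18 libraries (limma 3.58.1 in R 4.3.3, trended and robust variance), with 9 pairwise comparisons and 2 interactions. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values of genes below are from limma unless another tool is named. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1, so none is reported. Folds given as "at least" compare a mean with a floor of 3 reads per library in a group whose libraries were all at 0.

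The 22 fixed gene lists were each tested in the 9 pairwise comparisons with camera from limma, at a preset correlation of 0.01 and again with an estimated correlation, with adjusted p-values over the 198 tests. Named genes are, for each pairwise comparison, the 6 largest changes in each direction among called genes with a mean of at least 50 in the higher group and no overlap between the libraries, leaving out predicted genes, small RNAs, ribosomal protein pseudogenes and receptor segments. For each interaction the rule takes the 5 smallest p-values in each direction among called genes. For each list and pairwise comparison it takes those called among the 4 members with the smallest p-values, and always Cd4, Cd8a, Cd8b1, Foxp3, Zbtb7b and Runx3. The lists cover CD8 and intraepithelial identity, cytotoxicity, the regulatory core, gut effector regulatory cells, CD4 helper identity, naive and memory cells, Th1, Th17, follicular helper cells, inhibitory receptors, TGF-beta and homing, immediate early and dissociation-associated genes, proliferation, interferon response, glycolysis, cholesterol synthesis, and markers of epithelium, B and plasma cells, myeloid cells, gamma-delta T cells, innate lymphoid cells and stroma.

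The fit was tested on simulated data with 200 changed genes and each group's own dispersion. The common dispersion was 0.518 in IEL TR and 0.0863 to 0.114 in the other groups. In the 6 pairwise comparisons without IEL TR, 15% to 23% of 2-fold and 58% to 66% of 4-fold changes were recovered with at most 1 false call. In those with IEL TR the pooled variance was too small: 218 of 315 simulated calls were false for TR against SP, 312 of 407 for DP against TR, 288 of 398 for IEL against LP, and 33 of 76 for the TR interaction. Fitting only the groups compared gave 3 of 17, 1 of 8, 0 of 8 and 9 of 29 false calls, at the price of recovering fewer changes. The totals of the IEL TR comparisons are therefore also given under that fit and under library weights, as are genes shared between sites, and the members called of their main lists are given under that fit. With 200 genes changed, the simulated share of false calls does not carry over to real comparisons in which more genes differ. The simulation also gave the 3 IEL TR libraries 1 dispersion, while their library weights were 0.17, 0.684 and 0.531.

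The other settings tried were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, quantile normalisation, equal totals, variance without trend or robustness, only the groups compared, library weights, a replicate block, leaving out each library in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. For comparisons that do not hold IEL TR, fits without its library 1 and without all its libraries were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the reported values.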

Results

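The 18 libraries hold CD4 T cells of 1 clonal receptor, sorted from the small intestine of host mice 6 weeks after transfer. The cells came from the epithelium (intraepithelial, IEL) or from the lamina propria beneath it (LP). In each site 3 populations were sorted: cells with CD4 and CD8α together (DP), cells with CD4 and the Foxp3 reporter (TR, regulatory), and cells with CD4 but neither of the others (SP). Each of the 6 groups has 3 libraries, so n = 3 for every mean ± SD of normalised counts below. Recovered reads per library ran from 5093955 to 8851347. Changes are log2 fold changes, the first-named group minus the second, and ± after a log2 value is its standard error.

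The sorted genes followed the gates. Cd8a (ENSMUSG00000053977, GRCm38 chromosome 6, 71373427 to 71379173) stood at 5887 ± 874.8 in IEL DP and 3506 ± 207.2 in LP DP, against 48.06 ± 56.38 in IEL SP and 15.15 ± 6.261 in LP SP. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) stood at 118.1 ± 49.03 in IEL TR and 135.6 ± 22.16 in LP TR, against 21.66 ± 16.72 in IEL SP and 4.473 ± 5.371 in LP SP. Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) ran from 600.7 ± 28.96 in LP TR to 1034 ± 312.2 in LP SP. Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494), the partner chain of conventional CD8 T cells, ran from 49.19 in LP DP to 150.1 in LP TR. It was higher in IEL TR than IEL SP (1.29, adjusted p = 0.00515), a call lost with only the groups compared, and lower in DP than TR in the epithelium (-1.23, adjusted p = 0.00573), lost in the same fit, and in the lamina propria (-1.58, adjusted p = 0.0012). It did not pass for LP TR against LP SP (0.85, adjusted p = 0.0801). Cd8a and Foxp3 were sort criteria, so their differences describe the sort. Cd8a is on the CD8 and intraepithelial identity list and Foxp3 on the regulatory core list. Tests of these lists below therefore partly reflect the sort, and they were not repeated without these genes.

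**Figure D1:**
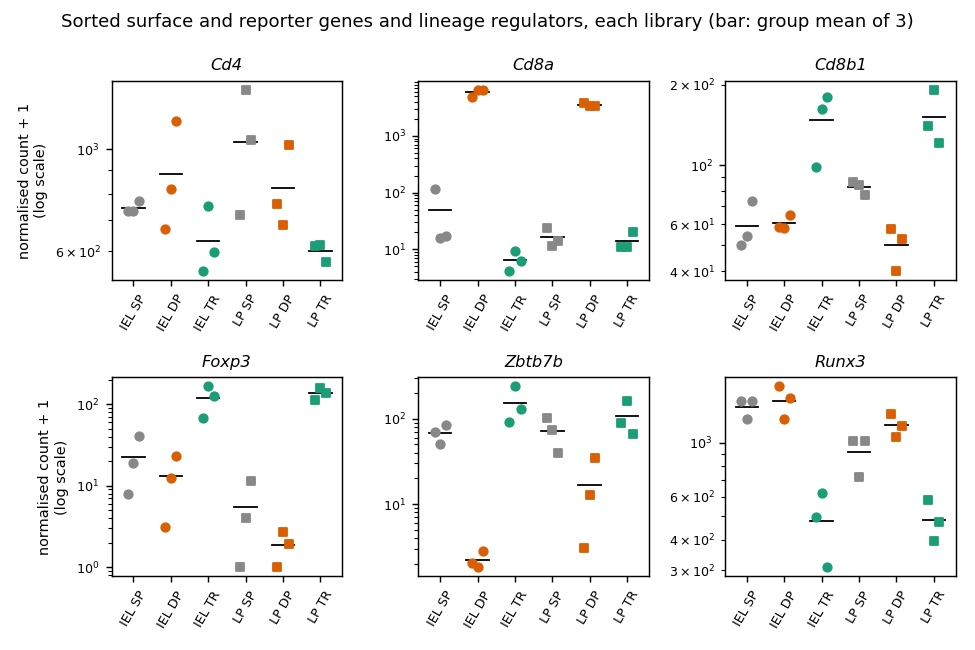
Normalised counts plus 1 on a log axis for the sorted genes and 2 lineage regulators in the 6 groups, 1 point per library and a bar at the mean of 3. Cd8a is high in both DP groups, Foxp3 in both TR groups, and Zbtb7b is lowest in IEL DP.

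Regulatory cells differed most from the other populations along the first principal component, which held 26.68% of the variance, with 15.6% on the second and 11.39% on the third. The IEL TR libraries were more variable than the others. Correlations between their libraries ran from 0.8045 to 0.8727, against 0.9238 to 0.9438 within the other groups. The median standard deviation of a gene was 0.5471 there and 0.3048 to 0.3488 elsewhere. IEL TR library 1 stood apart at 143.95 on the first and 137.04 on the second component. A fit that pools the variance over groups calls too many genes in comparisons with IEL TR, so the totals below, the shared genes and the main list members of those comparisons are also given with only the groups compared. Counts of the comparisons without IEL TR rose when its library 1 was left out, for LP TR against LP SP from 874 to 1274.

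**Figure D2:**
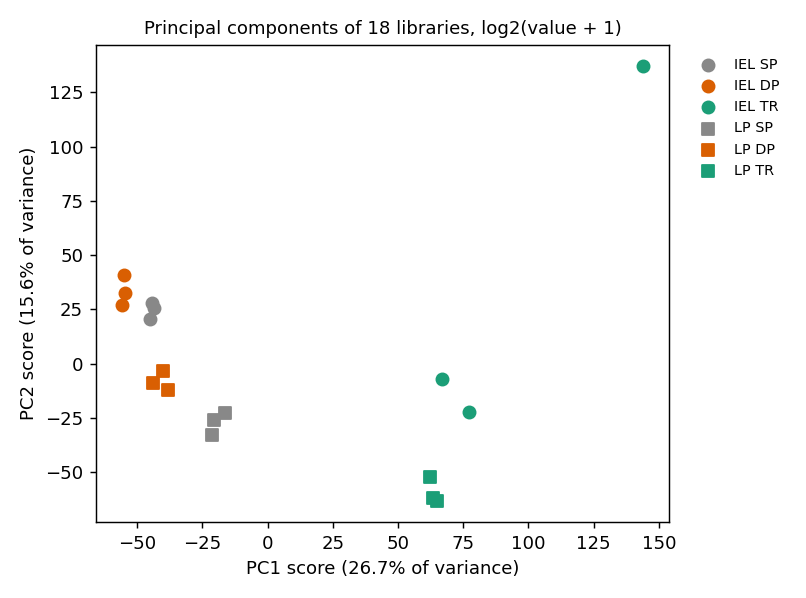
Scores of the 18 libraries on the first and second principal components of log2 values, with colour for the population and shape for the site. IEL TR library 1 lies apart at 143.95 and 137.04.

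The next question was what marks cells of the epithelium that gained CD8α while keeping CD4. IEL DP cells carried less of the CD4 helper list than IEL SP cells. Cd28, the costimulatory receptor, was lower (-2.55 ± 0.18, 184 ± 48.7 against 1062 ± 139, adjusted p = 1.13e-05), as was Icos, the inducible costimulator (-1.79 ± 0.14, adjusted p = 1.13e-05). Maf, a transcription factor of effector T cells on the gut effector regulatory list, was lower too (-1.96 ± 0.16, adjusted p = 1.31e-05). Zbtb7b (ENSMUSG00000028042, chromosome 3, 89377644 to 89394776), which encodes ThPOK, the regulator of helper identity, dropped from 67.07 ± 17.17 to 1.253 ± 0.5389 (-4.91 ± 0.68, adjusted p = 0.00788). Runx3 (ENSMUSG00000070691, chromosome 4, 135120652 to 135177990), which promotes the CD8 programme, did not pass (0.08, adjusted p = 1), and neither did Cd4 (0.20, adjusted p = 1).

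Of 15472 genes 17 were called in IEL DP against IEL SP, 2 higher and 15 lower, with 647 at an unadjusted p under 0.05. These 647 are below a share of 0.05 of the genes. The pooled variance also holds the wider spread of IEL TR, so this share does not show that no other genes differ. Of the CD4 helper list, 4 of 13 measured members were lower and 0 higher (5 lower and 1 higher adjusted over the list alone; list test adjusted p = 3.99e-06). The gut effector regulatory list had 2 of 20 lower (3 adjusted over the list alone, adjusted p = 7.43e-05) and the regulatory core 1 of 19 lower (5 adjusted over the list alone, adjusted p = 0.000836). Il18r1, an interleukin-18 receptor chain on the Th1 list, was lower (-2.36 ± 0.31, adjusted p = 0.00498), a call that ended with only the groups compared. It was the 1 called member of 14 on that list (2 lower adjusted over the list alone, adjusted p = 0.00425). No member passed over all genes on the lists of naive and memory cells (0 of 14, 2 lower adjusted over the list alone, adjusted p = 0.000128) and Th17 (0 of 10, 2 lower, adjusted p = 7.69e-05). Nor did any on follicular helper cells (0 of 10, 4 lower, adjusted p = 0.00265) or proliferation (0 of 20, adjusted p = 0.00177). All 4 lists shifted down. The CD8 and intraepithelial identity list shifted up, with Cd8a as the 1 called member of 19 (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.00313). Cd8a, the sorted gene, rose by 7.54, while the list had a median of 0.23 and a mean of 0.60, so how far the rest of the list shifted was not tested. Cytotoxicity shifted up too with 0 called of 21 (1 higher adjusted over the list alone, adjusted p = 0.00301). With an estimated correlation cytotoxicity (adjusted p = 0.114), Th1 (0.176), Th17 (0.0673), follicular helper (0.0522) and proliferation (0.357) were lost. The other lists did not pass; glycolysis (adjusted p = 0.853) had a median of 0.12 and a mean of -0.09, epithelium a median of -0.04 and a mean of 0.25, and innate lymphoid cells a median of -0.10 and a mean of 0.22.

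Several calls did not hold in every fit with 1 library left out. Zbtb7b was lost without IEL SP library 1 (adjusted p = 0.0549), IEL SP library 3 (0.0539) or IEL DP library 1 (0.062). S100a4, a calcium-binding protein (-4.63, adjusted p = 0.0467), was lost without any 1 of the 6 libraries (0.0697 to 0.288). Kbtbd11 (-3.99, 0.0435) and Tnfrsf18, the receptor GITR (-1.31, 0.0467), were lost without any 1 but IEL DP library 2 (0.0846 to 0.233 and 0.124 to 0.27), and Tnfsf11, the ligand RANKL (-1.83, 0.0467), without any 1 but IEL DP library 1 (0.12 to 0.288). The count of 17 fell to 7, 7 and 8 without IEL SP library 1, 2 or 3, to 6 and 7 without IEL DP library 1 or 3, and rose to 28 without IEL TR library 1. In simulated data 58% of 4-fold and 18% of 2-fold changes were recovered at this depth and spread, so the count does not bound how many genes differ.

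The same question was asked in the lamina propria. Ccl5, a chemokine of cytotoxic cells, was higher in LP DP than LP SP (2.01 ± 0.22, 32830 ± 4650 against 8178 ± 1395, adjusted p = 0.000476), as was Itgae, the CD103 chain that binds E-cadherin on epithelium (1.26 ± 0.13, 3929 ± 107 against 1636 ± 27.9, adjusted p = 0.000209). Lower were Maf (-2.42 ± 0.16), Cd28 (-1.84 ± 0.18, adjusted p = 0.000209), Icos (-1.34 ± 0.14, adjusted p = 0.00026) and Tspan32, a tetraspanin (-5.12 ± 0.50, 2.91 against 104, adjusted p = 0.000209). Also lower were Tnfrsf4, the receptor OX40 (-3.94 ± 0.42, adjusted p = 0.00034), and the chemokine receptor Ccr2 (-2.66 ± 0.38, adjusted p = 0.00419). Zbtb7b was lower without passing (-2.58, adjusted p = 0.178).

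In LP DP against LP SP 60 genes were called, 14 higher and 46 lower, with 1030 at an unadjusted p under 0.05. The CD8 and intraepithelial identity list rose with 3 of 19 members, the sorted gene Cd8a among them (6 higher and 1 lower adjusted over the list alone, adjusted p = 1.45e-08), and cytotoxicity with 2 of 21 (5 adjusted over the list alone, adjusted p = 0.000278). The CD4 helper list fell with 3 of 13 (8 lower and 1 higher adjusted over the list alone, adjusted p = 4.57e-10), and the gut effector regulatory list with 3 of 20 (8 lower and 1 higher, adjusted p = 4.66e-09). Th1 fell with 2 of 14 (6 lower, adjusted p = 9e-09), Th17 with 1 of 10 (6 lower, adjusted p = 7.71e-09) and follicular helper cells with 1 of 10 (5 lower, adjusted p = 2.72e-05). Naive and memory genes had 0 of 14 called and 2 lower adjusted over the list alone (adjusted p = 0.000779), and the regulatory core 3 of 19 lower (4 adjusted over the list alone, adjusted p = 0.0159). Interferon response (adjusted p = 0.0111) and myeloid markers (0.0134) shifted down with 0 members called. With an estimated correlation cytotoxicity (adjusted p = 0.06), the regulatory core (0.122), interferon (0.376) and myeloid markers (0.225) were lost. The TGF-beta and homing list did not pass and its test pointed up while its median was -0.18 and its mean -0.15.

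Other named genes in the lamina propria did not hold in every fit with 1 library left out. Crtam (2.74, adjusted p = 0.0323) was lost without any 1 but LP SP library 3 (0.0645 to 0.166), Ddc (1.56, 0.0323) without any 1 of the 6 (0.0551 to 0.143), and Cxcr6 (-1.35, 0.0323) likewise (0.0813 to 0.144). Mras (2.65, 0.021) was lost without LP SP library 1 or 2 or LP DP library 1 or 2 (0.0881 to 0.11). The chemokine Ccl4 (2.23, 0.0114) was lost without LP SP library 2 (0.0511) or LP DP library 1 (0.0619). Il22, a cytokine acting on epithelium (-6.25, 0.043), was lost without any 1 but LP DP library 1 (0.0944 to 0.2). It is on the Th17 list and on that of innate lymphoid cells, whose 8 genes summed to 181.38 to 626.82 in LP SP, 80.7 to 88.52 in LP DP and 16.16 to 81.56 in LP TR; whether such cells in LP SP gave the drops in Il22 and Th17 genes was not tested. S100a4 (-5.47, 0.00714) was lost without LP SP library 2 (0.0511). Folr4 (-4.32, 0.0102) was lost without LP SP library 2 (0.0578) or 3 (0.0503), and S100a6 (-3.98, 0.0323) without LP SP library 1 or 2 or LP DP library 1 or 3 (0.11 to 0.174). Il18r1 (-1.93, 0.011) was lost without LP SP library 3 (0.0545) or LP DP library 1 (0.0564), and Tnfsf11 (-1.87, 0.0196) without any 1 but LP DP library 3 (0.0535 to 0.0969). Tnfrsf18 (-1.45, 0.0112) was lost without LP SP library 2 (0.0524) or LP DP library 1 (0.0564) or 2 (0.0625), and the inhibitory receptor Lilrb4 (-1.24, 0.0117) without LP SP library 2 (0.0524) or 3 (0.0586) or LP DP library 1 (0.0564) or 2 (0.0645). Crtam, Mras, Ccl4, Ddc, Il22, S100a4, Folr4 and S100a6 also ended with only the groups compared, and Il22 with edgeR and DESeq2. The count of 60 fell to 20 and 34 without LP SP library 2 or 3, and to 33, 37 and 37 without LP DP library 1, 2 or 3.

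Across the sites, 11 genes were lower in DP than SP in both, where 0.0446 would be shared by chance: Tspan32, S100a4, Tnfsf11, Crim1, Icos, Cd28, Il18r1, Tnfrsf18, A630023P12Rik, Maf and Ifitm2, named after their values were seen. Only Cd8a was called higher in both. Whether the DP difference itself differed between sites was tested as an interaction in limma: 0 genes passed, with 590 at an unadjusted p under 0.05, below a share of 0.05 of the 15472 genes. DESeq2 called 1 gene, Ppp1r16b (0.82, adjusted p = 0.011), chosen after its value was seen, and edgeR 0. In simulated data 41% of 4-fold differences between the sites were recovered.

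Regulatory cells of the epithelium were then compared with SP cells beside them, to ask what separates the fates in 1 site. IEL TR cells held far more of the regulatory genes: Ikzf2, the transcription factor Helios (5.02 ± 0.29, 10800 ± 529 against 340, adjusted p = 4.78e-08), and Nrp1, neuropilin-1 (7.27 ± 0.41, 871 against 4.66, adjusted p = 3.51e-08). The same held for Capg, an actin-capping protein (5.76 ± 0.33, 6796 against 123, adjusted p = 4.38e-08), Ctla4, the inhibitory receptor (3.54 ± 0.27, adjusted p = 9.35e-07), and Areg, the growth factor amphiregulin (6.21, adjusted p = 1.63e-05). They held far less Ccl5 (-7.08 ± 0.22, 171 ± 64.1 against 21960 ± 1725, adjusted p = 9.88e-11) and Gzmk, a granzyme (-8.32 ± 0.73, 2.5 against 904, adjusted p = 3.34e-06). Lower too were Amica1, an adhesion molecule (-8.34 ± 0.38, 15.7 against 4751, adjusted p = 8.69e-09), and Itga1, the integrin α1 chain (-7.52 ± 0.66, adjusted p = 3.31e-06). Foxp3 itself was higher without passing (2.60, adjusted p = 0.0664).

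**Figure D3:**
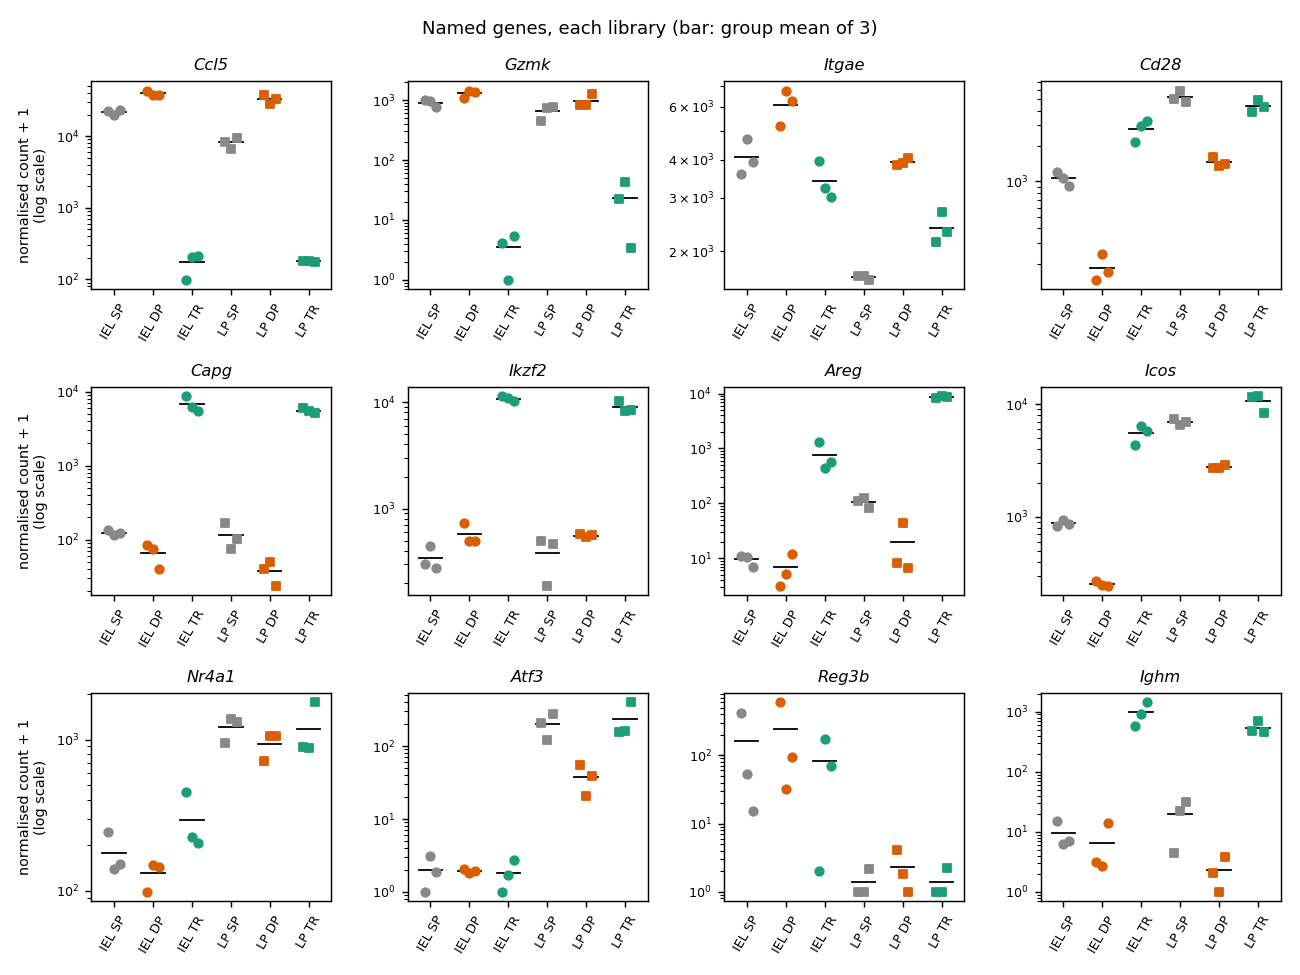
Normalised counts plus 1 on a log axis for 12 named genes in the 6 groups, 1 point per library and a bar at the mean of 3. Ccl5 and Gzmk are low and Capg and Ikzf2 high in both TR groups, and Atf3 is low in all IEL groups.

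In IEL TR against IEL SP 1799 genes were called, 940 higher and 859 lower. Simulated data with the spread of IEL TR and 200 changed genes gave 218 false among 315 calls, a share that does not carry over to the real count. With only the groups compared 450 were called (231 higher, 219 lower), with library weights 1080, and 380 in all 3 fits (207 higher, 173 lower). Without IEL SP library 1, 2 or 3 the count was 1194, 1165 and 1188. The balance turned with equal totals (600 higher and 1053 lower), with quantile normalisation (856 and 875) and without IEL TR library 2 (941 and 1207) or 3 (979 and 1187). Cd8a, lower in TR (-2.34, adjusted p = 0.0176), was lost without IEL TR library 1 (0.0517), with quantile normalisation, with library weights and with only the groups compared. Of the regulatory core 14 of 19 were higher and 1 lower (16 and 1 adjusted over the list alone, adjusted p = 7.54e-17), with Tnfrsf18 at 3.09. The gut effector regulatory list had 11 of 20 higher (12 higher and 1 lower adjusted over the list alone, adjusted p = 7.75e-12), with Icos at 2.64 ± 0.14, Maf at 2.77 and Ccr2 at 3.57. Follicular helper genes had 4 of 10 higher (4 adjusted over the list alone, adjusted p = 8.28e-05), with Cxcr5 at 6.41, and interferon response 8 of 20 (12 adjusted over the list alone, adjusted p = 1.57e-08, lost with an estimated correlation at 0.055), with Ifi27l2a at 3.11 ± 0.26. CD4 helper genes had 5 of 13 higher and 1 lower (5 and 2 adjusted over the list alone, adjusted p = 0.0127), with Cd28 at 1.38 and Gata3 at 1.87, and glycolysis 4 of 15 higher (adjusted p = 0.0226; 0.0998 and 0.388 with an estimated correlation, which ends both).

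Lower in IEL TR were the cytotoxic list (10 of 21 lower and 2 higher, 13 and 3 adjusted over the list alone, adjusted p = 1.64e-07), with Ccl4 at -7.29. CD8 and intraepithelial identity fell too (10 of 19 lower and 2 higher, the same adjusted over the list alone, adjusted p = 2.61e-06), with Cd244 at -6.66, Crtam at -6.64, Cd160 at -4.13 and Runx3 at -1.61 ± 0.23 (adjusted p = 0.000309). Other large drops were Tgfbr3, a TGF-beta co-receptor (-8.31 ± 0.45), and Qpct (-7.38). Cholesterol synthesis had 5 of 15 lower (adjusted p = 0.00376) and proliferation 4 of 20 lower and 1 higher (adjusted p = 0.0413); the latter was lost with equal totals (0.0737) and glycolysis with quantile normalisation (0.18). Gamma-delta T-cell markers fell (3 of 4 lower, 1 higher, adjusted p = 0.00704) with Tcrg-C4 (ENSMUSG00000076757, chromosome 13, 19344558 to 19352756) at -8.06 ± 0.43. B and plasma cell markers passed (1 of 7 higher, adjusted p = 0.0486) through Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), the IgM heavy chain, at 6.72 ± 0.76. With only the groups compared, the members called were 10 of 19 higher for the regulatory core, 8 of 20 higher for gut effector regulatory cells, 4 of 10 for follicular helper cells and 6 of 20 for interferon response. Cytotoxicity then had 8 of 21 lower and 1 higher, CD8 and intraepithelial identity 7 of 19 lower, CD4 helper 3 of 13 higher and 1 lower, glycolysis 2 of 15 higher, and cholesterol synthesis and proliferation 1 lower each. Of the lists lower in IEL TR and the cell markers, cholesterol (adjusted p = 0.388 with an estimated correlation), proliferation (0.529), gamma-delta (0.0543) and B-cell (0.239) lists were lost. Among the lists that did not pass, Th1 (adjusted p = 0.273) had a median of 0.11 and a mean of -0.82, inhibitory receptors (0.192) a median of 0.73 and a mean of -0.01, and immediate early genes (0.487) a median of 0.00 and a mean of -0.12. Among the largest rises were genes on none of the lists: H2-Ob, a class II chain, was at least 77.6-fold higher, Cd83 rose by 7.26, Cd81 by 6.96, Cybb, an NADPH oxidase subunit, by 6.76, Mmp9, a matrix metalloproteinase, by 6.68. Cd74, the invariant chain, rose by 3.23.

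The same comparison in the lamina propria gave a regulatory profile with Klrg1 and amphiregulin. LP TR cells had more Klrg1, a receptor of differentiated effector cells (7.16 ± 0.71, 3448 ± 326 against 24.6, adjusted p = 1.93e-05), and Areg (6.35 ± 0.63, 8501 ± 362 against 105, adjusted p = 1.86e-05) than LP SP cells. Higher too were Ikzf2 (4.67, adjusted p = 3.96e-07), Nrp1 (6.09, adjusted p = 5.79e-07), Capg (5.67, adjusted p = 1.96e-07) and Foxp3 (5.24). They had less Ccl5 (-5.51 ± 0.22, adjusted p = 3.75e-09), Ifng, the Th1 cytokine (-5.38 ± 0.48, 31.4 against 1091, adjusted p = 6.6e-06), Xcl1, a chemokine (-8.04 ± 0.84, adjusted p = 2.94e-05), Tgfbr3 (-8.19) and Tcf7, a factor of memory-like T cells (-3.89 ± 0.38, adjusted p = 1.75e-05). Il22 was at least 71.2-fold lower and Hid1 at least 21.5-fold lower in LP TR. Gpr83, a receptor of regulatory cells, was at least 31.5-fold higher, Gjb2 at least 44.1-fold and Ncmap at least 37.8-fold. Vill rose by 7.82 ± 0.66, Laptm4b by 7.80, and Qpct (-6.15) and Kcnk5 (-6.15) were lower.

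In LP TR against LP SP 874 genes were called, 501 higher and 373 lower. With only the groups compared there were 502 higher and 352 lower, against 231 and 219 in the epithelium. The pooled totals therefore do not rank the sites. The regulatory core had 15 of 19 higher (16 adjusted over the list alone, adjusted p = 8.38e-23) and the gut effector regulatory list 11 of 20 (11 adjusted over the list alone, adjusted p = 2.97e-11), with Ctla4 at 2.45, Maf at 1.56 and Ccr2 at 3.85. Interferon response was higher (6 of 20, 8 adjusted over the list alone, adjusted p = 5.61e-08), with Ifi27l2a at 2.77. TGF-beta and homing genes were higher (3 of 16 higher and 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.00693), with Gpr15, a gut homing receptor, at 4.66. Glycolysis (4 of 15, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00222) and follicular helper genes (3 of 10 higher and 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.0177) rose. So did B-cell markers (1 of 7, 5 adjusted over the list alone, adjusted p = 0.000845), with Ighm at 5.18 ± 0.76. Lower were cytotoxicity (10 of 21 lower and 2 higher, 12 and 3 adjusted over the list alone, adjusted p = 1.51e-09) and CD8 and intraepithelial identity (9 of 19 lower and 2 higher, 9 and 4 adjusted over the list alone, adjusted p = 1.45e-05). Immediate early genes fell (6 of 19, 10 adjusted over the list alone, adjusted p = 3.69e-08), with Nr4a2 at -3.55 and Fos at -1.45. Th1 genes fell (6 of 14, 6 lower and 1 higher adjusted over the list alone, adjusted p = 7.8e-05), with Tbx21 at -2.69, and gamma-delta markers (2 of 4, adjusted p = 0.00767). With an estimated correlation Th1 (adjusted p = 0.0673), follicular helper (0.107), interferon (0.0623), glycolysis (0.249), B-cell (0.056) and gamma-delta (0.0548) lists were lost. Medians and means differed in sign for naive and memory cells (-0.05 and 0.03), inhibitory receptors (0.14 and -0.04) and epithelium (0.01 and -0.36), none of which passed. Runx3 (-0.92, adjusted p = 0.0256) was lost without LP SP library 1 (0.0937) or 3 (0.101) or LP TR library 2 (0.119) or 3 (0.072), Itgae (0.53, 0.0217) without any 1 but LP TR library 1 (0.0519 to 0.109), and Cenpa (1.25) without LP SP library 3 (0.0558) or LP TR library 2 (0.0582).

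Both sites shared 342 genes higher in TR than SP, where 30.44 would be shared by chance, and 211 lower, where 20.71 would be. With only the groups compared they shared 125 higher (7.495 by chance) and 79 lower (4.982), and with library weights 318 (26.74) and 228 (20.29). The difference between the sites was tested as an interaction, which called 58 genes, 32 with a higher and 26 with a lower TR minus SP change in the epithelium, and 1610 at an unadjusted p under 0.05. More were lower than higher with equal totals (7 higher and 16 lower), no filter (25 and 29), no trend or robust variance (11 and 20) and DESeq2 (106 and 117). The same held without IEL TR library 1 (40 and 45), 2 (54 and 105) or 3 (55 and 110) or LP SP library 3 (12 and 20). Icos had the larger difference in the epithelium (2.05, adjusted p = 0.000268), with 874.4 in IEL SP and 5531 in IEL TR against 6981 and 10610 in the lamina propria, and Crem, a cyclic AMP response factor (1.94, adjusted p = 0.00986), and Pim1, a kinase (1.51, adjusted p = 0.00732), also did. In simulated data with 200 changed genes 33 of 76 interaction calls were false, a share that does not carry over to the real count. With only the groups compared 26 genes were called, with library weights 48, and 18 in all 3 fits. The count was 32 and 27 without IEL SP library 1 or 3, 159 and 165 without IEL TR library 2 or 3, 32 and 32 without LP SP library 2 or 3, and 32, 34 and 36 without LP TR library 1, 2 or 3.

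DP and TR cells were also compared directly, to ask how the CD8α and the Foxp3 fates differ within a site. In the epithelium DP cells had more Ccl5 (7.93 ± 0.22, 39660 ± 3402 against 171), Gzmk (8.83, 1288 against 2.5), Amica1 (8.32, adjusted p = 3.3e-09), Ccl4 (7.84, adjusted p = 3.3e-09) and Tgfbr3 (8.29, adjusted p = 1.39e-08). They had less Tspan32 (-9.34 ± 0.50, 3.17 against 2611, adjusted p = 1.37e-08), Folr4 (-8.69), Ebi3, a cytokine subunit (-8.25), Nrp1 (-8.13, adjusted p = 5.12e-09), Mmp9 (-7.89), Maf (-4.72, adjusted p = 6.41e-11), Icos (-4.43 ± 0.14, adjusted p = 4.36e-11) and Zbtb7b (-5.99, adjusted p = 3.35e-05), and at least 168-fold less Cd81. Runx3 was higher in DP (1.69). Foxp3 was lower (-3.52, adjusted p = 0.0136), a call lost with only the groups compared, with library weights and without IEL DP library 1 (0.0695).

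In IEL DP against IEL TR 2170 genes were called, 1035 higher and 1135 lower. Simulated data with 200 changed genes gave 312 false among 407 calls, a share that does not carry over to the real count. The balance was 1375 and 705 with equal totals, and 1398 and 1137 or 1374 and 1131 without IEL TR library 2 or 3. There were 640 with only the groups compared (275 higher, 365 lower), with library weights 1409, and 577 in all 3 fits (240 higher, 337 lower). Higher in DP were CD8 and intraepithelial identity (11 of 19 and 3 lower, the same adjusted over the list alone, adjusted p = 1.05e-07), with Itga1 at 7.76 and Cd244 at 7.68. Cytotoxicity rose too (10 of 21 and 1 lower, 14 and 2 adjusted over the list alone, adjusted p = 4.66e-09), with Ctsw, a lymphocyte protease, at 2.05. So did cholesterol synthesis (6 of 15, 8 adjusted over the list alone, adjusted p = 0.00039), with Lss at 2.20. Lower was the regulatory core (14 of 19 and 1 higher, 16 and 1 adjusted over the list alone, adjusted p = 5.28e-17), with Capg at -6.72 and Tnfrsf4 at -7.68. The gut effector regulatory list was lower (12 of 20, 14 lower and 1 higher adjusted over the list alone, adjusted p = 5.03e-12), with Areg at -6.89. Follicular helper genes (6 of 10, 7 adjusted over the list alone, adjusted p = 8.04e-06) and interferon response (9 of 20, 11 adjusted over the list alone, adjusted p = 3.97e-08) were lower. So were CD4 helper genes (5 of 13 and 2 higher, the same adjusted over the list alone, adjusted p = 0.000845) and glycolysis (3 of 15, adjusted p = 0.0283, lost with quantile normalisation at 0.185). Gamma-delta markers were higher (3 of 4 and 1 lower, adjusted p = 0.00801), with Tcrg-C4 at 9.09, and Ighm lower (-7.55). With only the groups compared the members called were 10 of 19 higher for CD8 and intraepithelial identity, 8 of 21 higher and 1 lower for cytotoxicity, 11 of 19 lower for the regulatory core, 9 of 20 lower for gut effector regulatory cells and 5 of 10 lower for follicular helper cells. Interferon response and CD4 helper genes then had 5 lower each, cholesterol synthesis 1 higher and glycolysis 0. Under an estimated correlation interferon (adjusted p = 0.06), glycolysis (0.401), cholesterol (0.302) and gamma-delta (0.055) lists were lost.

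In the lamina propria DP cells had more Tgfbr3 (8.85, adjusted p = 2.05e-08), Ccl5 (7.52, adjusted p = 4.16e-11), Xcl1 (7.15, adjusted p = 5.84e-05), Amica1 (7.13, adjusted p = 2.32e-08) and Qpct (7.08, adjusted p = 1.84e-07) than TR cells. They had less Areg (-9.31 ± 0.63, adjusted p = 2.46e-07), Tspan32 (-8.62, adjusted p = 5.95e-08), Folr4 (-7.87, adjusted p = 3.02e-06), Ebi3 (-7.74, adjusted p = 1.4e-05), Tnfrsf13b, a receptor for B-cell survival factors (-7.34, adjusted p = 0.000462), and Foxp3 (-6.28, adjusted p = 0.000247), and at least 109-fold less Vill. The T-box factor Tbx21 (3.27), Ifng (5.21), Tcf7 (3.36) and Runx3 (1.30, adjusted p = 0.00175) were higher in DP, while Klrg1 (-7.04), Ccr7, a lymph-node homing receptor (-6.20), Gata3 (-3.03) and Maf (-3.98) were lower.

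In LP DP against LP TR 1375 genes were called, 506 higher and 869 lower. Higher were CD8 and intraepithelial identity (11 of 19 and 2 lower, adjusted p = 6.99e-11) and cytotoxicity (13 of 21 and 2 lower, adjusted p = 2.84e-11), with the same counts adjusted over the list alone. Higher too were immediate early genes (4 of 19 and 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 9.81e-05), with Nr4a2 at 4.96 and Fos at 1.83, and gamma-delta markers (1 of 4 and 1 lower, adjusted p = 0.0361). Lower were the regulatory core (16 of 19, also 16 adjusted over the list alone, adjusted p = 3.36e-21) and the gut effector regulatory list (11 of 20, 14 lower and 1 higher adjusted over the list alone, adjusted p = 1.11e-14). Follicular helper genes were lower (4 of 10, 7 adjusted over the list alone, adjusted p = 1.53e-05). CD4 helper genes (6 of 13 and 2 higher, 8 and 2 adjusted over the list alone, adjusted p = 0.00611) and interferon response (8 of 20, 12 adjusted over the list alone, adjusted p = 4.25e-10) fell. So did glycolysis (5 of 15, 9 lower and 1 higher adjusted over the list alone, adjusted p = 9.09e-05), with Pgk1 at -1.02, and B-cell markers (1 of 7, adjusted p = 0.0112), with Ighm at -8.07. With an estimated correlation CD4 helper (adjusted p = 0.0673), immediate early (0.0662), glycolysis (0.134), B-cell (0.125) and gamma-delta (0.113) lists were lost. Across both sites 308 genes were higher and 538 lower in DP than TR, where 33.85 and 63.75 would be shared by chance. With only the groups compared 128 were higher (10.61 by chance) and 261 lower (24.75), and with library weights 345 (38.02) and 512 (60.03).

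The next comparisons set the same population in the epithelium against the lamina propria, to ask what the tissue adds. SP cells of the epithelium had more Itgae (1.31 ± 0.13, 4078 against 1636, adjusted p = 1.25e-05), Ccl5 (1.44, 21960 against 8178, adjusted p = 0.00109) and Crtam (2.59, adjusted p = 0.00685). They had less Icos (-3.00 ± 0.14, 874 against 6981, adjusted p = 1.04e-08), Cd28 (-2.30, adjusted p = 2.02e-06), Ctla4 (-2.80, adjusted p = 1.25e-05) and Tnfrsf4 (-4.29). They also had less of immediate early genes, which receptor signals and tissue dissociation both raise, with Atf3, a stress-response factor, at 0.993 against 201 (-6.73 ± 0.55, adjusted p = 2.14e-06), Nr4a1 at -2.79 (adjusted p = 0.000113), Dusp1 at -2.17 and Junb at -1.56. Il22 (-5.41, adjusted p = 0.0172) was lost without IEL SP library 2 (0.0768) or 3 (0.09) or LP SP library 1 (0.0859) or 3 (0.0523), and with edgeR and DESeq2. Other large drops were Dusp4 (-6.16, adjusted p = 0.000439), Ramp3 (-5.56, adjusted p = 3.96e-06), Gramd3 (-5.14) and Sgtb (-5.07). Bhlhe40, a factor of cytokine-producing T cells (-3.73, adjusted p = 2.16e-07), Rora (-1.37) and the TGF-beta antagonist Skil (-1.50) were lower too.

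In IEL SP against LP SP 862 genes were called, 271 higher and 591 lower. Immediate early genes fell with 10 of 19 members (12 adjusted over the list alone, adjusted p = 1.52e-13). The gut effector regulatory list fell with 7 of 20 (11 lower and 1 higher, adjusted p = 6.52e-06) and Th1 with 6 of 14 (7 lower, adjusted p = 5.55e-05). CD4 helper genes fell with 4 of 13 (6 lower and 1 higher, adjusted p = 0.000239), the regulatory core with 4 of 19 (6 lower and 2 higher, adjusted p = 0.043), the counts in parentheses adjusted over the list alone. Th17 fell with 2 of 10 (adjusted p = 0.0245) and naive and memory genes with 1 of 14 (adjusted p = 0.0317). CD8 and intraepithelial identity rose with 4 of 19 (7 adjusted over the list alone, adjusted p = 0.000175). Epithelial markers rose with 1 of 16 (6 adjusted over the list alone, adjusted p = 0.00301), and myeloid markers fell with 1 of 9 (3 adjusted over the list alone, adjusted p = 0.00958). Under an estimated correlation the regulatory core (adjusted p = 0.193), naive (0.132), Th1 (0.0645), Th17 (0.302), epithelial (0.114) and myeloid (0.197) lists were lost. Cytotoxicity did not pass (adjusted p = 0.835; median 0.36, mean -0.32). The largest rises did not hold in every fit with 1 library left out: Reg3b, an antimicrobial lectin of epithelium (5.75, adjusted p = 0.0353), was lost without any 1 but IEL SP library 3 (0.0711 to 0.162). Cited4 (3.90, 0.0482) was lost without any 1 of the 6 (0.0627 to 0.184), Exog (3.58, 0.0451) without any 1 but LP SP library 3 (0.0941 to 0.158), and Det1 (3.31, 0.0424) without any 1 but LP SP library 2 (0.0796 to 0.128). Nckap1 (3.42, 0.016) was lost without IEL SP library 3 (0.0677) or LP SP library 2 (0.078), and Zfp790 (3.07, 0.0228) without IEL SP library 1 (0.111) or 2 (0.08) or LP SP library 1 (0.101) or 2 (0.0937). The count of 862 fell to 534 and 541 without IEL SP library 1 or 3 and to 570 without LP SP library 3, and rose to 1304 without IEL TR library 1.

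DP cells of the epithelium likewise had less Icos (-3.44 ± 0.14, 253 against 2760, adjusted p = 3.3e-09), Cd28 (-3.00, adjusted p = 1.59e-07), Ctla4 (-3.61, adjusted p = 1.1e-06) and Ramp3 (-7.12 ± 0.48, 1.84 against 390) than DP cells of the lamina propria. Immediate early genes were lower, with Nr4a1 at -2.85 (adjusted p = 0.000114), Atf3 at -4.18 (adjusted p = 0.00026), Dusp1 at -2.34 (adjusted p = 1.13e-05) and Cd69, an activation and retention marker, at -1.88 (adjusted p = 0.000307). Taf4b (-5.78), Maff, Vps37b (-5.00) and Fabp5l2 (-4.99), whose reads can be shared with its near copy Fabp5, were among the largest drops. Bcl11b, a T-cell identity factor (0.65, adjusted p = 0.00897), and Ifi47 (1.34, adjusted p = 0.00304) were higher.

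In IEL DP against LP DP 847 genes were called, 274 higher and 573 lower. Immediate early genes fell with 11 of 19 members (13 adjusted over the list alone, adjusted p = 2.32e-14). The gut effector regulatory list fell with 4 of 20 (4 adjusted over the list alone, adjusted p = 0.00696) and CD4 helper genes with 4 of 13 and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.0138). Naive and memory genes fell with 2 of 14 (adjusted p = 0.0346) and proliferation with 1 of 20 (2 adjusted over the list alone, adjusted p = 0.0116). Th1 genes fell with 3 of 14 (6 lower and 3 higher adjusted over the list alone, adjusted p = 0.0393) and inhibitory receptors with 4 of 14 (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0455), both lost with quantile normalisation (0.0599 each). Myeloid markers fell with 1 of 9 (adjusted p = 0.0385). Epithelial markers rose with 4 of 16 (8 adjusted over the list alone, adjusted p = 0.000171), cholesterol synthesis with 1 of 15 (adjusted p = 0.0476) and gamma-delta markers with 0 of 4 called (adjusted p = 0.0428). Only the immediate early list held with an estimated correlation (adjusted p = 0.00291); gut effector regulatory cells (0.0673), CD4 helper (0.104) and epithelial markers (0.055) were among those lost. Reg3b (5.95, adjusted p = 0.0299) was lost without any 1 but IEL DP library 2 (0.0523 to 0.134). Fabp2, an enterocyte fatty-acid binding protein (5.91, 0.0213), was lost without IEL DP library 3 (0.115) or LP DP library 2 (0.0851) or 3 (0.0796). Krt20, an epithelial keratin (3.71, 0.0299), was lost without any 1 of the 6 (0.0585 to 0.116). Cpt2, a mitochondrial fatty-acid enzyme (3.93, 0.0215), was lost without IEL DP library 2 (0.101) or 3 (0.0551) or LP DP library 1 (0.0967) or 2 (0.0965). Mettl22 (higher, adjusted p = 0.00414) and the chemokine Cxcl10 (-4.88, 0.00652) ended with only the groups compared. Nipal1 (3.53, 0.0224) was lost without IEL DP library 1 (0.0946) or 2 (0.0887) or LP DP library 1 (0.102) or 3 (0.0658). Metrnl (3.16, 0.0158) was lost without IEL DP library 2 (0.0566) or 3 (0.0652), Itgae (0.62, 0.00975) without IEL DP library 2 (0.0521), and Ahr, a sensor of dietary ligands (-1.66, 0.011), without IEL DP library 3 (0.0579). The count of 847 fell to 544, 542 and 457 without IEL DP library 1, 2 or 3 and to 491 and 541 without LP DP library 2 or 3, and rose to 1271 without IEL TR library 1.

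Regulatory cells of the epithelium had less Rora (-2.31 ± 0.15, 1260 against 6305, adjusted p = 1.22e-06), Areg (-3.63 ± 0.63, 767 against 8501, adjusted p = 0.00301), Atf3 (-7.02 ± 0.55, 0.81 against 239), Ctla4 (-1.71, adjusted p = 0.00173), Bhlhe40 (-2.03) and Skil (-0.87, adjusted p = 0.000401) than those of the lamina propria. Prim2, a DNA primase subunit (-5.68, adjusted p = 5.12e-06), Ndc80, a kinetochore protein (-5.52, adjusted p = 2.32e-05), Agpat9 (-5.55) and Fabp5l2 (-5.47) were among the largest drops. Prim2 averaged 0.29 in IEL TR, so the size of its drop depends on the added 1. Irg1 (-5.67, adjusted p = 0.0182) was lost without IEL TR library 1 (0.0604) or LP TR library 1 (0.0726). Icos (-0.94), Nr4a1 (-2.00), Nr4a3 (-2.81), Rrm2 (-3.18), Tcf7 (2.08) and Bcl11b (0.76) were called only until the fit was limited to the groups compared.

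In IEL TR against LP TR 1008 genes were called, 386 higher and 622 lower. Simulated data with 200 changed genes gave 288 false among 398 calls, a share that does not carry over to the real count. With only the groups compared there were 93 (5 higher, 88 lower), with library weights 507, and 84 in all 3 fits. Of the 5 higher in all 3 fits, 4 were Dctn5 (0.89), Brd7 (1.73), Mgat2 (1.13) and AI504432 (1.71), named after their values were seen. Klhl42 (3.18), Pdik1l (3.32), Tfb1m (3.03), Zfp28 (3.51), Thumpd2 (3.34) and Zfp790 (3.31), the largest rises, all ended with only the groups compared. Zfp28 also ended without IEL TR library 1 (0.0954) or LP TR library 1 (0.137), Thumpd2 without IEL TR library 1 (0.0861) or LP TR library 1 (0.106) or 3 (0.058), and Zfp790 without LP TR library 1 (0.057). Gut effector regulatory genes fell with 4 of 20 (8 adjusted over the list alone, adjusted p = 0.00301), proliferation with 4 of 20 (12 adjusted over the list alone, adjusted p = 2.41e-06) and glycolysis with 1 of 15 (adjusted p = 0.0386). None of these held with an estimated correlation (adjusted p = 0.0548, 0.152 and 0.436). With only the groups compared, 1, 0 and 0 members were called. Immediate early genes did not pass (adjusted p = 0.437), with a median of 0.02 and a mean of -0.53. The count was 1597 without IEL TR library 3 and 619 and 659 without LP TR library 1 or 2. SP and DP shared 85 genes higher and 392 lower in the epithelium, where 4.799 and 21.89 would be shared by chance. Stroma markers, of 3 measured members, and innate lymphoid markers, of 5, passed as lists in none of the 9 comparisons, though 1 of the 3 was lower in LP TR than in LP SP. Il22, 1 of the 5, was called lower in LP DP and LP TR than in LP SP and in IEL SP than in LP SP.

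Markers of other cells moved with the groups. Ighm stood at 455.33 to 1431.66 in the TR libraries and at most 30.14 in the others. The sum of 10 epithelial markers was 1422, 265 and 93 in the IEL SP libraries, 1798, 135 and 996 in IEL DP, 54, 478 and 146 in IEL TR, and 2 to 9 in the LP libraries. Tcrg-C4, a gamma-delta receptor constant segment with near copies, averaged 748.4 in IEL SP, 1535 in IEL DP, 176 in LP SP and 679 in LP DP, against 1.97 and 4.883 in the TR groups. In the SP and DP libraries 2 other gamma segments were low, Tcrg-V7 at 0 to 9.1 and Tcrg-C1 at 1.7 to 50.75. Whether gamma-delta T cells gave the Tcrg-C4 reads was not tested.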

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

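The tests of B cells, of cells rich in Lyz2, Csf1r and C1q genes, of lost transcripts, of fewer reads and of the epithelial markers' own correlation were chosen only after the result was seen; the splits, the abundant transcript and epithelial RNA in the 85 shared genes were chosen before.

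A test of the difference between sites called 58 genes in which the TR difference from SP differed between epithelium and lamina propria, and the 9 given here are among the 5 with the smallest p-values in each direction, with 1 left out. Gp49a differed by 1.98 (2.31 in the epithelium and 0.32 in the lamina propria, adjusted p = 0.000268), though Lilrb4, a near copy, can share its reads. Icos differed by 2.05 (2.64 and 0.59). Pim1 differed by 1.51 (2.31 and 0.80) and Crem by 1.94. Casp4, an inflammatory caspase, differed by 1.13 (0.86 and -0.27, adjusted p = 0.0128). Prim2 differed by -5.75 (-5.78 and -0.03, adjusted p = 0.000811), with IEL TR at 0.29, so the size of its change depends on the added 1. Odf2l differed by -6.78 (-5.06 and 1.72, adjusted p = 0.0115), with IEL TR at 0 and LP SP at 2.727, so the size of these changes depends on the added 1. Zfp667 differed by -6.06 (-3.92 and 2.14, adjusted p = 0.0128), with IEL TR at 0.58, so its size depends on the added 1 too. Id2, an inhibitor of E proteins, differed by -1.74 (-1.04 and 0.70, adjusted p = 0.0128). The calls of Zfp667 and Id2 both ended with only the groups compared. Reassigning the residuals gave as many genes in 1 of 100 regroupings, the real one, with 3 at the highest of the others, but that test assumes equal spread, which IEL TR breaks. The DP interaction had 0 genes, so 100 of 100 regroupings had to give as many (2 at the highest) and the count says nothing about chance.

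For the pairwise counts the 6 libraries make only 10 splits, too few for a share under 0.05, and 1 split, the real one, gave the real count in each. Every other split mixes the groups compared, so a true difference between them widens the spread and lowers the count. The low counts of the other splits therefore do not show what chance alone gives. The real counts and the highest of the other splits were 17 and 0 for IEL DP against SP, 60 and 3 for LP DP against SP, 1799 and 1 for IEL TR against SP, 874 and 1 for LP TR against SP, 2170 and 4 for IEL DP against TR, 1375 and 0 for LP DP against TR, 862 and 1 for SP between sites, 847 and 1 for DP and 1008 and 11 for TR.

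Ighm, H2-Ob, Cd83, Cd81, Cybb and Tnfrsf13b, picked after their values were seen, were higher in TR libraries. Cells rich in Lyz2, Csf1r, C1qa, C1qb and C1qc are argued against as the source: all 6 TR libraries had fewer reads of these 5 genes (2.1 to 43.83) than LP SP library 2 (463.5), with more Cybb (360.22 to 1130.16 against 5.97). The 17-gene myeloid list summed to 343.54 to 1177.2 in IEL TR against 167.14 to 257.35 in IEL SP but to 461.35 to 1204.1 in LP TR against 411.47 to 1551 in LP SP, and without Cd74 to 5.25, 67.37 and 277.96 against 107.75 to 212.29 and to 103.21 to 300.73 against 277.02 to 1044.93, so it gives no support to other myeloid cells and does not exclude them. For B cells, 3 of the 6 libraries had Cd79a, Ms4a1 and Igkc together under 10% of Ighm (0.546%, 0.442% and 1.13%) and the others 16.6%, 56.2% and 13.1%. Those 3 were IEL TR libraries 1 and 2 and LP TR library 1. There the 3 genes summed to 3.15, 4.12 and 5.41 beside Ighm at 576.77, 931.49 and 477.04. These values argue against B cells as the source of Ighm in those libraries. In LP TR library 2, however, Igkc stood at 383.01 and Igj, another B and plasma cell marker, at 471.3. The bound of 4 libraries was set after the values were seen and a bound of 3 would have been met. B cells stay open in the other libraries and for the other genes, although a Foxp3-GFP gate should remove them. Expression by the regulatory cells themselves stays open too and was not tested.

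IEL TR library 1 lay apart from libraries 2 and 3. Fewer reads are argued against, since its 7108325 recovered reads (7.108 on the test's scale) exceeded the median of 5903164.5. One transcript taking a large share is argued against too: without Gm26870, at 7.752% of its total, its correlations with libraries 2 and 3 were 0.8174 and 0.8057, below the 0.8725 between those. Loss of transcripts from a small or degraded sample is a candidate explanation: 115 genes had at most 1 read there but at least 50 in both mates, against at most 10 in any other library. No biological explanation was tested.

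Genes higher in IEL than LP could come from epithelial RNA carried into the sort. Over 9 epithelial markers the median correlation with the sum of the others was 0.776, which is consistent with carried RNA for those that followed it, such as Reg3b (0.924), but Fabp1 (-0.0614) and Fabp2 (-0.12) did not. For the 85 genes higher in both SP and DP the median correlation with the marker sum was -0.0256, at percentile 50.88 of random lists. These genes were chosen by calls in both populations, while the sum ran from 93 to 1422 within IEL SP. Genes that follow so variable a sum were less likely to be called, so the test cannot decide the question. Epithelial RNA stays open for this set, whether it follows the sum or, as for Fabp1 and Fabp2, does not. So does the tissue itself, an untested biological explanation.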

How the results depend on the processing

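The fit without IEL TR libraries and the one without IEL TR library 1, for comparisons that do not hold them, were tests chosen only after the result was seen; the others were planned. Counts here are of called genes, with the pooled fit first, and the cause was not tested except where a fit uses fewer libraries or the simulated false calls show it. Of 9273 alternatives over 484 named gene results, 8573 kept direction and side of the threshold, 700 lost the call and 0 turned direction. All 484 were called in the pooled fit, so none could gain a call. Only the groups compared lost 106 calls, library weights 37, edgeR and the fit without trend or robust variance 30 each, equal totals 27, no filter 25, quantile 19, pseudocount 8 14, pseudocount 0.5 13, DESeq2 9, the replicate block 3, and a mean of at least 50 and the fit without IEL TR libraries 1 each.

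IEL DP against SP had 17: pseudocount 8 gave 9, quantile 27, no trend or robust variance 11, only the groups compared 9, library weights 51, edgeR 8, DESeq2 61 and no IEL TR libraries 33. LP DP against SP had 60: weights gave 125, DESeq2 194 and no IEL TR libraries 119. IEL TR against SP had 1799: only the groups compared gave 450 and weights 1080. LP TR against SP had 874: weights gave 1343 and no IEL TR libraries 1470. IEL DP against TR had 2170: only the groups compared gave 640 and weights 1409. LP DP against TR had 1375, and weights gave 2139. SP between sites had 862: weights gave 1537, DESeq2 1388 and no IEL TR libraries 1533. DP between sites had 847: weights gave 1916, DESeq2 1414 and no IEL TR libraries 1472. TR between sites had 1008: only the groups compared gave 93, weights 507 and DESeq2 1667. The DP interaction had 0: no filter gave 1, no trend or robust variance 3 and DESeq2 1. The TR interaction had 58: quantile gave 38, equal totals 23, no trend or robust variance 31, only the groups compared 26 and DESeq2 223. List calls at the preset correlation numbered 90 of 198, and 40 with the estimated one.

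Leaving out 1 library gave 6 to 28, 20 to 82, 1165 to 2166, 590 to 1274, 1455 to 2535, 975 to 1854, 534 to 1304, 457 to 1271 and 619 to 1597 in the order above, 0 to 0 and 27 to 165 for the DP and TR interactions, and 82 to 99 for lists. The replicate block gave 25, 87, 1925, 1014, 2289, 1503, 1009, 978, 1138, 0, 76 and 89 in that order. In their residuals all 18 libraries correlated most, on average over the other groups, with libraries of their own number. Something shared within a number is therefore likely, though the labels do not say what, and the main fit leaves it out. With equal totals the median of all genes was -0.195 in IEL TR against SP (-0.0524 before), 0.236 in IEL DP against TR (0.0555), 0.141 in DP between sites (0.052) and -0.136 in the TR interaction (-0.0363). The counts higher and lower were then 600 and 1053, 1375 and 705, 359 and 408, and 7 and 16.

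The spread of IEL TR is a limit. In simulated data the pooled fit gave 218 false of 315 calls, 312 of 407, 288 of 398 and, for the interaction, 33 of 76; edgeR gave 125 of 212 and DESeq2 649 of 775 for TR against SP, and library weights 17 of 60.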

Other observations

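The values here come from no test chosen after the result was seen. Epcam and Cdh1 are adhesion genes on the epithelial list that T cells also express. Cdh1, E-cadherin, was lower in TR than SP in the epithelium (-5.69, adjusted p = 1.17e-06) and the lamina propria (-4.95). It averaged 314.6 in IEL SP, 294.4 in IEL DP, 186.7 in LP SP and 293.1 in LP DP, against 5.463 in IEL TR and 4.787 in LP TR. Epcam averaged 329.6 in IEL TR and 195.8 in LP TR, against 61.43, 34.72, 59.69 and 17.52 in IEL SP, IEL DP, LP SP and LP DP. It did not pass for TR against SP in the epithelium (2.55, adjusted p = 0.0856) or the lamina propria (1.84, adjusted p = 0.319). Against TR it was lower in LP DP (-4.76, adjusted p = 0.00321) and in IEL DP (-3.42, adjusted p = 0.0207), where the call was lost without IEL DP library 2 (0.0912) and with library weights.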
